A study of Mus musculus with 11 samples.

How the data were processed

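The samples are hypothalamus pieces from mice aged 60 to 70 postnatal days, per the labels, of which 5 were wild type (WT) and 6 were heterozygous for a mutated Myt1l gene (Het). Each of the 11 libraries is 1 animal, and all 11 columns of the deposited table were used. Per the labels, RNA was extracted with a Zymo kit and libraries were made with the SMARTer Ultra Low RNA kit. The labels name Trimmomatic, Bowtie2, STAR and HTSeq with genome build mm10 and give no versions. Whether the counting used strand is not given in the sources used here, so genes whose exons overlap on opposite strands share an uncertain part of their reads.

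The deposited values are log2 CPM (counts scaled by library size) plus a small constant, after a correction that the name of the deposited table gives as RUVr, the removal of unwanted variation estimated from residuals. Negative values down to -3.574, which is the lowest value of every column, show the log scale. Every column also has the same upper quartile over genes, 5.473. Back-transformed values minus the floor were whole multiples of 1 step per library for 100% of values, within a tolerance of 0.02 of a whole number. The whole-number corrected counts behind the table summed to 22921048 to 24941704 per library. These totals were taken after the correction, so the depth of the raw reads is unknown. Reads without molecular identifiers are not independent molecules, so a counting error computed from these totals would be too small. The interval given for Myt1l was not computed from them. It comes from the limma standard error, which covers the spread between libraries left after the correction.

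The number of factors taken out by the correction, its design and the gene filter are not given in the sources used here. Over 12079 genes, the log corrected counts, with each gene centred on its mean over the 11 libraries, had 1 direction across libraries with almost no variation left. Its singular value was 0.279, against 17.4 to 34.1 for the other directions. That direction had a correlation of -0.00047 with genotype, -0.00046 with sex and 0.18 with their product across libraries. Genotype and sex were therefore both spared by the correction, and residual variation was removed around them. A test that treats the corrected values as raw then has too small an error estimate.

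The planned analysis assumed linear CPM. Since the table held log2 values, CPM were recovered by the back-transform, and the planned test was then run on log2(CPM + 0.5). Genes with a mean CPM of at least 1 over all libraries were tested, which kept 13184 of 14864 genes and left out 1680. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with genotype and sex as terms, and a genotype by sex term for the interaction. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Myt1l was also tested by a two-sided exact permutation of genotype within sex. Fits on fewer libraries kept the genes that passed the filter over all 11. Coordinates, transcript lengths and GC content came from the GENCODE annotation of the same build, in which 14856 genes of the table were found.

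Before the data were examined, 31 gene lists, the design, the rule for named genes and most of the alternatives were fixed. Of these lists, 30 had the minimum of 5 measured members, and the pituitary list was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists, and beside it with camera at an estimated correlation and with fry. For Het against WT, the named genes were Myt1l and the 12 highest and 12 lowest log2 fold changes past the threshold that went the same way in both sexes, without predicted-gene names. For each list, up to 4 members with the smallest p-values were named. For the interaction, the 5 smallest p-values were taken. For sex, a list of sex chromosome genes and the 5 highest and 5 lowest changes outside it were taken. Xist and Tsix are not analysed here, and 2 genes that the rule takes are not reported here.

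The method was tested on simulated changes in simulated tables, drawn with each gene's mean level and residual spread in this table and with counting error. That spread is the one left after the correction, and genes were drawn independently, so the recovery below may be too high for this table. For Het against WT, 37.3%, 68.7% and 95.5% of genes changed by 1.25, 1.5 and 2 fold were recovered, with 5 false calls among 12984 unchanged genes. For sex the shares were 20.9%, 71.6% and 92.4%, with 8 false calls. For the interaction they were 0%, 11.9% and 48.5%, with 3 false calls. A second simulation asked what a residual-based correction does to a data set without any genotype effect. It used 25 sets of 13184 genes with 1 hidden factor and assumed settings, so it is a guide and not a measurement of this table. Before correction, the highest number of genes called in a set was 1. After correction the median was 13, the highest was 2395, and 8 of the 25 sets had at least 453 calls.

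Alternatives to the pseudocount, filter, threshold, scaling, error model, covariates, blocks and list tests were run, and each library was left out in turn. The runs without the libraries labelled WT replicate 11 and Het replicate 9, and those with transcript length and GC trends or a striatal covariate, were added after the data were examined. Between libraries of one group, none of the 25 pairs was a duplicate: the lowest chi-square per gene was 9.22, and library correlations ranged from 0.9751 to 0.9902.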

Results

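RNA was sequenced from the hypothalamus of adult mice that carried either 2 working copies of Myt1l or a heterozygous mutation in it. Myt1l encodes a zinc finger transcription factor of neurons. The WT group had 2 females and 3 males, and the Het group had 3 females and 3 males. Corrected counts totalled 22921048 to 24941704 per library, and 1 corrected count stood for 0.04174 to 0.04225 CPM. The descriptions carry identifier prefixes whose meaning the labels do not give. Prefix 14308 holds 2 WT and 2 Het libraries, all male, prefix 14309 holds 2 WT and 4 Het libraries of both sexes, and prefix 14111 holds only WT replicate 4. A block by prefix therefore gives WT replicate 4 no weight. Its genotype differences equal those of the run without that library, so these runs are not separate evidence.

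Myt1l itself did not separate the groups. Its level was 76.3 ± 15.9 CPM (SD, n = 5) in the libraries labelled WT and 76.3 ± 26.9 CPM (SD, n = 6) in those labelled Het. The gene (ENSMUSG00000061911) lies on mm10 chromosome 12 from 29528384 to 29923213, and Gm20208 overlaps its exons on the opposite strand. In the libraries labelled WT replicates 4, 6, 3, 7 and 11, the values were 70.5, 83.5, 89.3, 87.2 and 51.1 CPM. In those labelled Het replicates 2, 4, 7, 5, 8 and 9, they were 64.1, 64.3, 65.0, 58.7, 75.9 and 130 CPM. The library labelled Het replicate 9 was thus 1.98 times the mean of the other Het libraries, and the library labelled WT replicate 11 was 0.618 times the mean of the other WT libraries. The fitted difference was -0.01 on the log2 scale (SE 0.18, 95% confidence interval -0.42 to 0.39), with a limma adjusted p of 0.98 and an exact permutation p of 0.845, where 200 arrangements allow 0.005 at best. Without these 2 libraries, means were 82.6 ± 8.46 CPM in 4 WT and 65.6 ± 6.27 CPM in 5 Het libraries, a log2 difference of -0.32, which is no test of Myt1l because the 2 were left out for their Myt1l level. Within prefix 14308 the difference was -0.40, and within prefix 14309, which holds both libraries, it was 0.31. A mutated transcript that is still made and counted adds to a level measured over the whole gene, so this level is an incomplete check of the labels.

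Rnaseh1, which encodes a ribonuclease that degrades RNA paired with DNA and lies 869 kb from Myt1l, followed the same order. It was chosen after its values were seen, as the gene among 19 tested neighbours within 2 Mb that separated the other 9 libraries. Those labelled WT had 15.2 to 17.0 CPM and those labelled Het 12.2 to 13.8 CPM, while WT replicate 11 had 13.0 CPM and Het replicate 9 had 17.7 CPM. In every genotype comparison that follows, groups are as labelled, and values without these 2 libraries stand beside the counts.

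**Figure D1:**
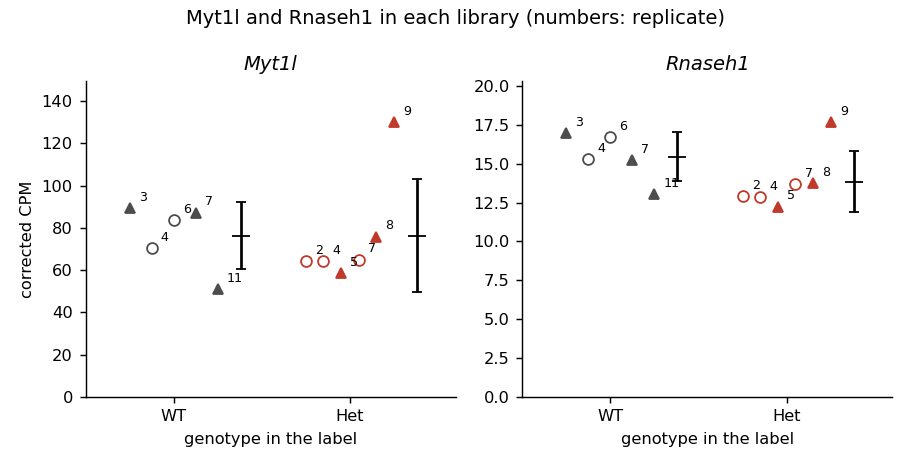
Levels of Myt1l and of its neighbour Rnaseh1 in CPM (y axis, from 0) for each of the 11 libraries by labelled genotype (x axis), with replicate numbers beside the points and the mean and SD as bars. Libraries labelled Het replicate 9 (130 CPM of Myt1l) and WT replicate 11 (51.1 CPM) lie outside the range of the others in their groups.

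Among genes that passed the test, activity-induced genes such as Egr2 and Arc and the channel gene Scn4b were among the highest in the libraries labelled Het, and Clec3b, Hspb1 and Eno3 were among the lowest. Egr2, an activity-induced transcription factor (ENSMUSG00000037868, mm10 chromosome 10 from 67535475 to 67542188), was 1.23 ± 0.59 CPM in WT (SD, n = 5) and 3.74 ± 1.36 CPM in Het (SD, n = 6), a log2 difference of 1.26 (SE 0.27, limma adjusted p = 0.0224). Scn4b, a sodium channel beta subunit (ENSMUSG00000046480, chromosome 9 from 45138395 to 45154152), rose from 10.4 ± 1.92 to 22.8 ± 8.19 CPM, and all 6 Het values were above all 5 WT values. Arc, an activity-induced gene of synaptic plasticity, rose from 26.3 ± 8.32 to 51.4 ± 10.2 CPM. Inhba, a subunit of activin, rose from 5.18 ± 1.90 to 9.45 ± 1.23 CPM. Cd4, a T cell coreceptor that microglia and macrophages can also express, rose from 5.07 ± 1.47 to 11.6 ± 5.32 CPM. In the other direction, Clec3b, which encodes the secreted protein tetranectin, fell by 1.0 on the log2 scale, from 5.57 ± 0.81 to 2.86 ± 1.45 CPM (SE 0.24, limma adjusted p = 0.0339). Eno3, a glycolytic enolase best known from muscle, fell from 5.73 ± 0.48 to 3.07 ± 0.61 CPM, and all 6 Het values were below all 5 WT values. Hspb1, a small heat shock protein, fell from 9.11 ± 2.82 to 5.38 ± 2.50 CPM.

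In all, 453 of 13184 genes passed the adjusted threshold between the genotypes, 303 higher and 150 lower in Het. All 453 had the same sign in females and males. A fit over both sexes makes this likely for the genes it calls, so it is no separate support. The log2 differences of the 453 genes ran from -1.0 to 1.26, with a median size of 0.385. The other genes among the 12 highest were CK137956, Sytl5 (a binding partner of Rab proteins in vesicle traffic), Sh3rf2, Adra2b (an alpha-2 adrenergic receptor), Prkch (a protein kinase C), Filip1 and Syndig1l, with log2 differences of 0.85 to 1.10. The other genes among the 12 lowest were Dyrk3, Emilin2, Tmem252, Map3k6, Tcim, Ptgr1, Lrmda, Arrdc2 and Ttc9b, with log2 differences of -0.93 to -0.72. Reads of Syndig1l, Tcim and Ttc9b are uncertain in part, since Gm48573, Gm26714 and Map3k10 overlap them on the opposite strand. Without the 2 libraries in doubt, 229 genes passed, 203 of them among the 453, and 14 of the 24 genes named as highest or lowest were among those that passed. The balance of higher and lower genes moved with scaling: centring each library on its median gave 233 higher and 243 lower, and quantile normalization gave 362 higher and 102 lower. Blocking by prefix gave 300 genes, prefix 14308 alone 6, Avp (-0.71) among them, and prefix 14309 alone 16. From the limma fit with the interaction, 0 genes passed in females (1743 at an unadjusted p under 0.05) and 9 in males (1927 at an unadjusted p under 0.05), and the difference between the sexes is tested separately.

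Since the correction removed residual variation around the genotypes, these adjusted p-values are too small by an amount that the table cannot give: with 1 residual degree of freedom taken off 189 genes passed, and 8 of 25 simulated sets without any genotype effect had at least 453 calls after such a correction. Single libraries also set the count, which was 820 without WT replicate 3, 140 without WT replicate 6, 180 without Het replicate 9, 191 without Het replicate 8, 219 without WT replicate 4, 220 without Het replicate 2, 243 without WT replicate 7 and 287 without Het replicate 4, and of the 24 highest and lowest genes 8 passed whichever library was left out: Cd4, Sytl5, Scn4b, Arc, Inhba, Filip1, Syndig1l and Eno3. Among the 11 such runs, Adra2b did not pass in 1, Map3k6 and Lrmda in 2, Egr2 and Arrdc2 in 3, Prkch and Clec3b in 6, Ptgr1 in 7, CK137956, Sh3rf2, Dyrk3, Hspb1 and Ttc9b in 8, and Emilin2, Tmem252 and Tcim in 9. Of the genes named from lists in what follows, Hcrt, Avp, Oxt, Meis2, Sox11, Camk2a, Gad2, Scn2b, Kcna1, Foxp1, Slc1a2, Drd1, Rasd2, Pde10a, Nr4a1 and Rorb also passed whichever library was left out. In the same runs, Gal, Scn2a and Fosl2 did not pass in 4, Adcyap1, Tcf7l2 and Hlf in 5, Pdyn, Gabrb2 and Dcn in 6, and Ncam1 in 7. Dpysl3, Plxna4, Grin2b and Gjb6 did not pass in 8, Pmch, Fabp7, Slc2a1, Phf21a, Rtp4 and Rpl13 in 9, and Gpr17 and Rps2 in 10.

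**Figure D2:**
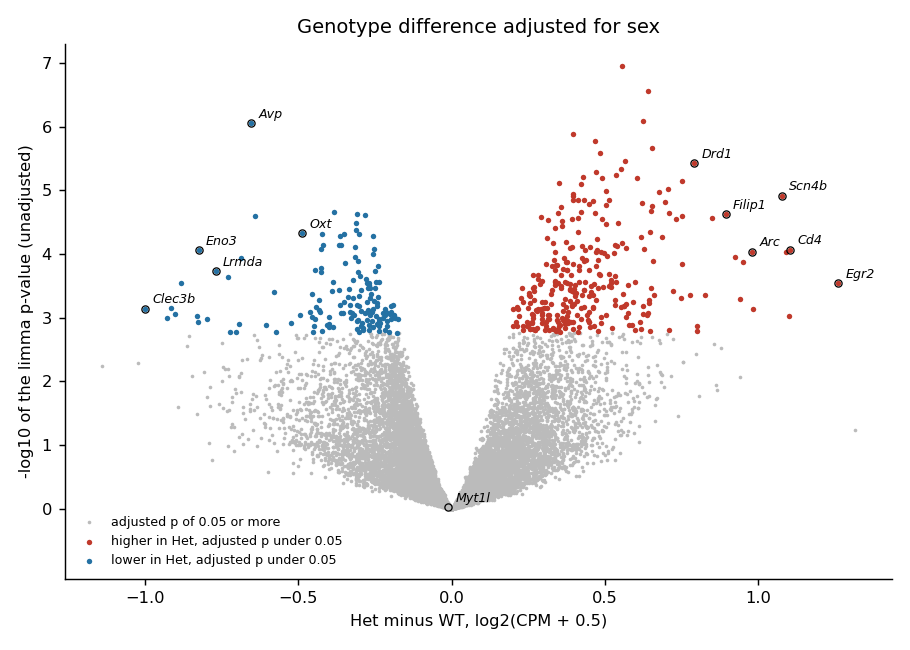
Each of the 13184 tested genes by its Het minus WT difference in log2(CPM + 0.5) (x axis) and the negative log10 of its unadjusted limma p (y axis), with the 453 genes past the adjusted threshold in colour. Myt1l sits at -0.01, and Egr2 (1.26) and Clec3b (-1.0) mark the ends of the range of the 453 genes.

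Genes of synapses and voltage-gated channels were higher in the libraries labelled Het. Of 40 measured synapse genes, 7 rose and 33 did not pass, 31 had a positive difference, and the median was 0.18 (camera adjusted p = 7.93e-08). Adjusted over the list alone, 19 rose. Camk2a, a calcium-dependent kinase of excitatory synapses, rose from 124 ± 25.1 to 199 ± 20.6 CPM, and Grin2b, an NMDA receptor subunit, from 9.54 ± 1.61 to 13.9 ± 1.27 CPM. Gad2, which makes GABA, and Gabrb2, a GABA receptor subunit, rose by 0.34 and 0.39 on the log2 scale. Of 35 channel genes, 6 rose (10 adjusted over the list alone) and 29 did not pass, with a median of 0.25 (camera adjusted p = 5.28e-07). They include the sodium channel subunits Scn4b, Scn2b (0.31) and Scn2a (0.40) and the potassium channel Kcna1 (0.57). Of 31 autism and neurodevelopmental risk genes, 4 rose (10 adjusted over the list alone) and 27 did not pass, with a median of 0.17 (camera adjusted p = 6.58e-07). Among them were the transcription factor Foxp1 (0.68), and Grin2b and Scn2a again. The calls of these 3 lists, and of no other list, also held with an estimated correlation, with adjusted p = 0.00372 for synapse and for channel genes and 0.0398 for risk genes. With each library's trend on transcript length and GC content taken out, risk genes were at 0.030 and did not pass (camera adjusted p = 0.107), synapse genes were at 0.096 and channel genes at 0.17, both with a camera adjusted p of 0.000867, and with the striatal mean as a covariate risk genes were at 0.27. Within groups of genotype and sex, the mean of risk genes went against that of striatal markers over the 11 libraries (r -0.84, rho -0.89, exact permutation p = 0.00231 for both, the smallest that 432 arrangements can give, adjusted over 29 lists 0.0335 and 0.067, r -0.86 without the 2 farthest libraries). Reads of Grin2b and Foxp1 are uncertain where other annotated genes overlap their exons.

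Markers of the striatum, the forebrain region above and in front of the hypothalamus, were higher as well. All 14 measured markers had a positive difference, 5 rose (9 adjusted over the list alone) and 9 did not pass, and the median was 0.45 (camera adjusted p = 7.93e-08, but adjusted p = 0.225 with an estimated correlation). Drd1, the D1 dopamine receptor (ENSMUSG00000021478, chromosome 13 from 54051183 to 54055705), rose from 25.5 ± 5.53 to 43.3 ± 9.50 CPM. Rasd2, a small GTPase rich in striatal neurons, and Pde10a, a phosphodiesterase of the same cells, rose by 0.62 and 0.55 on the log2 scale. The median was 0.47 without the 2 libraries in doubt. Of 11 thalamic markers, 1 rose (2 adjusted over the list alone) and 10 did not pass, with a median of 0.195 (camera adjusted p = 0.0473, adjusted p = 0.357 with an estimated correlation). The riser was Tcf7l2, a transcription factor of the Wnt pathway (0.39), and the list was at 0.098 and did not pass without the 2 libraries in doubt. It did not pass either without WT replicate 3 (0.19), WT replicate 7 (0.16), WT replicate 11 (0.15), Het replicate 5 (0.23), Het replicate 7 (0.24), Het replicate 8 (0.19) or Het replicate 9 (0.14). In females alone the thalamic median turned to -0.089, and the list did not pass with quantile normalization (0.21), within prefix 14309 (0.245), with fry, without shared genes (0.19), with the length and GC trend taken out (0.050) or with the striatal mean as a covariate (0.17). Of 12 cortical and hippocampal markers none passed (2 rose adjusted over the list alone), and the median was 0.11 (camera adjusted p = 0.224). It was 0.025 without WT replicate 3, 0.046 without WT replicate 11, 0.071 without Het replicate 5 and 0.17 without WT replicate 7, and the list passed in none of these.

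Immediate early genes, which neurons switch on within minutes of activity, included 6 that rose (7 adjusted over the list alone, with 1 lower) and 10 that did not pass. The median of the 16 was 0.34 (camera adjusted p = 0.00421, adjusted p = 0.349 with an estimated correlation). Nr4a1, a nuclear receptor, rose from 26.5 ± 4.45 to 44.4 ± 8.30 CPM, and Fosl2, a member of the AP-1 family, from 4.14 ± 0.61 to 6.83 ± 0.92 CPM. Among 16 circadian clock genes, 2 rose (also 2 adjusted over the list alone), 14 did not pass, and the median was 0.18 (camera adjusted p = 0.00528, adjusted p = 0.225 with an estimated correlation). The 2 were Rorb (0.47), a nuclear receptor, and Hlf (0.36), a PAR bZIP transcription factor. Striatal markers were higher in the same group, with the median of 0.45 given above. Between the 11 libraries within groups of genotype and sex, the mean of immediate early genes went with the striatal mean (r 0.82, rho 0.90, exact permutation p = 0.00231 and 0.00463, adjusted over 29 lists 0.0335 and 0.0671, r 0.96 without the 2 farthest libraries), where 0.00231 is the smallest p that 432 arrangements can give. With the striatal mean as a covariate neither list passed, with medians of 0.085 for immediate early and 0.14 for clock genes. In males alone the medians were 0.22 and 0.11 and both passed, and with the length and GC trend taken out clock genes were at 0.12 and passed.

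Several hypothalamic peptide genes were lower in the libraries labelled Het, while the calls of the lists that hold them depended on the setting. Avp, which encodes vasopressin (ENSMUSG00000037727, chromosome 2 from 130580620 to 130582554), fell by 0.65 on the log2 scale, from 466 ± 87.1 CPM (SD, n = 5) to 320 ± 106 CPM (SD, n = 6; SE 0.085, limma adjusted p = 0.00292). Oxt, which encodes oxytocin and lies beside Avp (ENSMUSG00000027301, chromosome 2 from 130576173 to 130577054), fell by 0.49 on the log2 scale (SE 0.089). Adcyap1, the gene for the peptide PACAP, fell from 40.6 ± 4.87 to 31.2 ± 3.38 CPM, while Pdyn, the dynorphin precursor, rose from 107 ± 15.4 to 141 ± 28.2 CPM. Of the 27 measured neuroendocrine genes, 3 fell, 1 rose and 23 did not pass, with a median of -0.17 (camera adjusted p = 0.0152, adjusted p = 0.114 with an estimated correlation), and 8 fell and 1 rose adjusted over the list alone. Of 30 genes of feeding and energy balance, 3 fell (5 adjusted over the list alone) and 27 did not pass, with a median of -0.10 (camera adjusted p = 0.0223, adjusted p = 0.114 with an estimated correlation). Hcrt, the orexin precursor that drives wakefulness and feeding, fell from 1233 ± 212 to 967 ± 142 CPM, Gal, which encodes galanin, from 368 ± 26.0 to 295 ± 35.6 CPM, and Pmch, the melanin-concentrating hormone precursor, from 540 ± 92.6 to 409 ± 112 CPM. Parpbp overlaps Pmch on the opposite strand. Lepr, the leptin receptor, had a log2 difference of -0.75 (SE 0.24) and did not pass (limma adjusted p = 0.0879). Among 28 regional transcription factors of the hypothalamus, Meis2 rose (0.55) and 27 did not pass, with 2 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.758. Of 11 monoamine and cholinergic genes none passed, with a median of -0.105 (camera adjusted p = 0.538). This median was -0.060 without WT replicate 3 or Het replicate 2, -0.062 without WT replicate 6, -0.063 without Het replicate 9 and -0.21 without Het replicate 8. It turned to 0.021 in males alone, 0.067 in prefix 14308 and 0.082 with the striatal mean as a covariate, without passing. Striatal markers, with a median of 0.45, were higher in the group in which both peptide lists were lower. Both lists passed without the 2 libraries in doubt, but neither the feeding nor the neuroendocrine list passed in prefix 14309 alone (medians -0.11 and -0.13), in females alone (-0.039 and -0.12), with the length and GC trend taken out (-0.046 and -0.090) or with the striatal mean as a covariate (-0.042 and -0.086). The neuroendocrine list also did not pass with no covariate (-0.16) and was at -0.11 with quantile normalization, and the feeding list did not pass without WT replicate 3 (-0.089) and was at -0.155 in males alone.

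**Figure D3:**
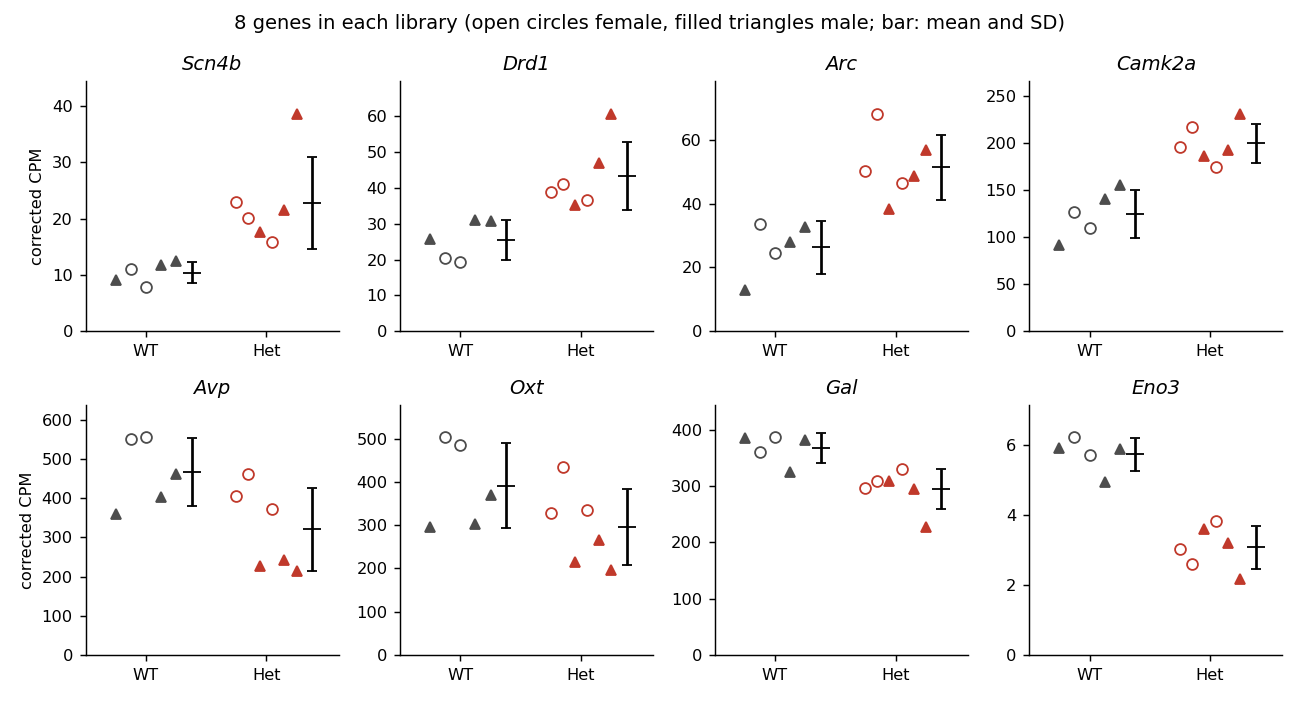
Level in CPM (y axis) of 8 genes in each library, by labelled genotype (x axis), with sexes marked by symbol and the mean and SD as bars. Scn4b, Drd1, Arc and Camk2a were higher and Avp, Oxt, Gal and Eno3 lower in libraries labelled Het, and for Avp and Oxt the female libraries lie above the male libraries of the same genotype on average.

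Protein synthesis and respiration genes were lower by small amounts on average, and libraries of the 2 groups overlapped. All 39 cytosolic ribosomal protein genes had a negative difference, 2 fell (14 adjusted over the list alone) and 37 did not pass, and the median was -0.17 (camera adjusted p = 3.27e-08, but adjusted p = 0.413 with an estimated correlation). These were Rpl13, from 1985 ± 263 to 1668 ± 154 CPM, and Rps2, from 343 ± 46.0 to 291 ± 26.9 CPM, and reads of ribosomal protein genes are uncertain because many have near-identical pseudogenes. All 27 nuclear-encoded respiratory chain genes were negative too, none passed (8 fell adjusted over the list alone), and the median was -0.16 (camera adjusted p = 2.40e-06, adjusted p = 0.357 with an estimated correlation). Cox8a, a subunit of cytochrome oxidase, was 793 ± 135 CPM in WT and 652 ± 102 CPM in Het. The mitochondrially encoded genes had a median of -0.13 over 13 members and did not pass (camera adjusted p = 0.0531). The libraries labelled WT replicates 3 and 6 stood apart: their ribosomal list means, centred over libraries on the log2 scale, were 0.285 and 0.231, against -0.091 to 0.058 in the other WT and -0.16 to 0.096 in the Het libraries. They were also highest for respiratory (0.17 and 0.21), mitochondrially encoded (0.21 and 0.27) and blood genes (1.0 and 1.19). Ribosomal genes were at -0.11 without WT replicate 3, -0.34 in prefix 14308, -0.11 in females and -0.071 with quantile normalization, and with the length and GC trend taken out at -0.059, and passed each time, but not with fry or with the striatal mean as a covariate (-0.016). Respiratory genes were at -0.31, -0.097 and -0.064 in prefix 14308, in females and with quantile normalization and at -0.067 with the striatal covariate, and passed, but not with the length and GC trend taken out (-0.047). Mitochondrially encoded genes passed without WT replicate 4 (-0.16), WT replicate 7 (-0.15), WT replicate 11 (-0.16) or Het replicate 9 (-0.15), without the 2 libraries in doubt (-0.18), with a prefix block (-0.16), in prefix 14308 (-0.21), in females alone (-0.18), with no covariate and with no filter. They were at -0.064 without WT replicate 6 and turned to 0.070 with the length and GC trend taken out, without passing.

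The lists of interferon and glucocorticoid response genes and of meningeal markers passed on the lower side, each with calls that were lost in some settings. Of 15 interferon genes, 1 fell (2 adjusted over the list alone) and 14 did not pass, with a median of -0.28 (camera adjusted p = 0.00421, adjusted p = 0.357 with an estimated correlation). It was Rtp4, a chaperone of receptor transport, with a log2 difference of -0.53 (SE 0.13). The interferon list did not pass in females alone (-0.20) or with fry, and it was at -0.48 with the striatal mean as a covariate. None of 12 glucocorticoid response genes passed (7 fell adjusted over the list alone), and the median was -0.23 (camera adjusted p = 0.0223, adjusted p = 0.413 with an estimated correlation). Pdk4, a kinase that restrains glucose oxidation, was 6.25 ± 1.33 CPM in WT and 3.92 ± 1.19 CPM in Het. With the striatal mean as a covariate the median of this list turned to 0.0088. The list did not pass in females alone (-0.16), with the length and GC trend taken out (-0.17), with fry, or without WT replicate 7 (-0.22), Het replicate 8 (-0.23) or WT replicate 6 (-0.17), and it was at -0.41 in prefix 14308. All 12 markers of meninges and fibroblasts were negative, 1 fell (2 adjusted over the list alone) and 11 did not pass, with a median of -0.37 (camera adjusted p = 0.0125, adjusted p = 0.505 with an estimated correlation). It was Dcn, which encodes decorin, a proteoglycan of connective tissue, from 61.7 ± 2.97 to 49.5 ± 9.64 CPM. The list did not pass without the 2 libraries in doubt (-0.28), nor without Het replicate 8 (-0.18) or WT replicate 11 (-0.23), nor in females alone (-0.115), with fry or with the striatal mean as a covariate (-0.57), and was at -0.58 in males alone. All 6 blood genes were negative with a median of -0.67 and did not pass (camera adjusted p = 0.0864). They did pass without WT replicate 4 (-1.04), WT replicate 11 (-0.89), Het replicate 4 (-0.77) or Het replicate 9 (-0.79), without the 2 libraries in doubt (-0.98), with a prefix block (-1.04) and in prefix 14308 (-1.44). Without WT replicate 6 they were at -0.35, without WT replicate 3 at -0.43. Hba-a1, a hemoglobin chain with a near-identical copy, had 319 ± 197 CPM in WT and 176 ± 54.5 CPM in Het.

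The lists of glia, vessels, progenitors and development did not pass. Slc1a2, the main glutamate transporter of astrocytes, rose from 160 ± 17.2 to 207 ± 16.3 CPM while Gjb6, an astrocyte gap junction gene, fell from 333 ± 31.5 to 279 ± 28.3 CPM, and the 16 astrocyte genes had a median of -0.08 (camera adjusted p = 0.634). Gpr17, a receptor of maturing oligodendrocyte precursors, rose by 0.35, and its list of 12 had a median of 0.07 (camera adjusted p = 0.0923), with 0.11 without WT replicate 3 and 0.039 without WT replicate 7. Camera adjusted p-values were 0.732 for 20 genes of myelinating oligodendrocytes, 0.355 for 17 of microglia, 0.732 for 17 of endothelium and mural cells, 0.634 for 11 of ependyma and tanycytes, and 0.165 for 9 of the choroid plexus. Adjusted over the list alone, 3 ependymal genes and 1 endothelial gene fell, 3 genes of oligodendrocyte precursors rose, 2 astrocyte genes rose and 1 fell, and no gene passed for microglia, myelinating oligodendrocytes or the choroid plexus. Oligodendrocyte precursors passed with fry, microglia in females alone (-0.16), and the choroid plexus in prefix 14309 alone (-0.55). Single members past the threshold were Slc2a1, the glucose transporter of brain endothelium (-0.30), and Fabp7, a fatty acid binding protein of radial glia (-0.27). In the list of immature neurons and neurite outgrowth, Sox11 (0.50), Plxna4 (0.62), Dpysl3 (0.28) and Ncam1 (0.20) rose and 24 of 28 did not pass, with a median of 0.00 (value -0.00129, camera adjusted p = 0.624). Phf21a, a partner of histone demethylases, rose (0.36) among 15 genes of the MYT family and its corepressor partners (camera adjusted p = 0.27). The lists of neural progenitors and cell cycle (16 genes) and of Notch and Wnt signalling (30 genes) had camera adjusted p-values of 0.862 and 0.732. For 7 of the 30 lists the median, the mean and the test differed in sign, and none of these passed: hypothalamic transcription factors, immature neurons, progenitors, Notch and Wnt, myelinating oligodendrocytes, endothelium, and ependyma.

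In total 14 of 30 lists passed with camera's preset correlation, 7 higher and 7 lower, against 3 with an estimated correlation and 10 with fry, which asks whether a list moves on balance without comparing it with other genes. With the preset correlation, other splits of the 11 libraries into 5 and 6 called a median of 5 lists and up to 15. The camera adjusted p-values at that setting, small as they are, are thus a weak guide to chance. Blocking by prefix gave 16 lists, and prefixes 14308 and 14309 alone gave 16 and 12. Without the 2 libraries in doubt 14 passed, 6 higher and 8 lower, and 8 passed with the length and GC trend taken out and 5 with the striatal covariate.

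**Figure D4:**
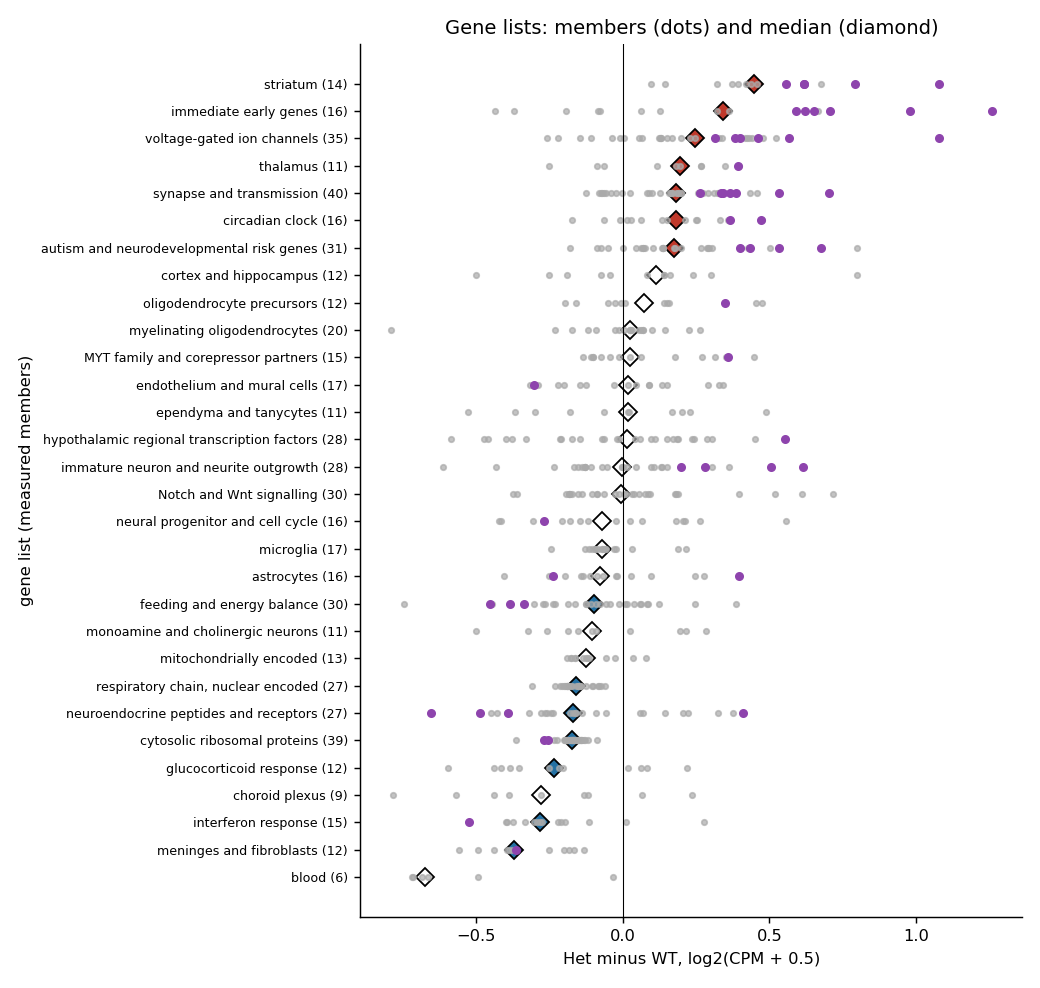
Het minus WT difference in log2(CPM + 0.5) (x axis) for the measured members of each of the 30 tested lists (y axis), with members past the adjusted threshold as filled purple dots, and medians as diamonds coloured where camera at its preset correlation passed. The medians run from -0.67 for blood to 0.45 for the striatum.

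Whether genotype acted differently in females and males was tested next, and no gene passed. The 5 genes with the smallest p-values were Ccdc186, which takes part in dense-core vesicle formation, Ppp1r21, Nkain2, Cfap46, a protein of the ciliary axoneme, and Prr5l. For Ccdc186 the Het minus WT difference was -0.15 in females and 0.60 in males, a difference of 0.75 (SE 0.16). For Nkain2 it was 0.79 in females and -0.40 in males, and for Cfap46 -1.30 and 0.18. The smallest limma adjusted p was 0.982, and 613 genes had an unadjusted p under 0.05. With a block by prefix 0 passed, as did 0 without the 2 libraries in doubt, and in prefix 14309 alone 1 passed, Myt1l itself (1.71, limma adjusted p = 0.0434), in a subset whose only males are the 2 libraries in doubt. The test recovered 11.9% of simulated 1.5 fold differences, so most differences of that size were not detectable here. The direction emptied by the correction also had a correlation of 0.18 with the product of genotype and sex. Part of such a difference may therefore have been taken out before the test, which the simulation does not cover.

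Sex chromosome genes separated the sexes, and the hormone genes Avp and Oxt were higher in females, with values that overlapped between the sexes. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were listed at 0 in all 5 females, with 67.7 ± 7.93, 22.1 ± 3.06, 7.69 ± 1.95 and 6.01 ± 0.55 CPM in males (SD, n = 6). Of their X-linked partners, Ddx3x (0.48), Eif2s3x (0.54) and Kdm5c (0.69) were higher in females, and Kdm6a was 8.08 ± 1.24 CPM in females and 5.74 ± 0.76 CPM in males without passing (limma adjusted p = 0.174). Avp was 469 ± 83.0 CPM in females (SD, n = 5) and 318 ± 105 CPM in males (SD, n = 6), a log2 difference of 0.67 (SE 0.085, limma adjusted p = 0.00103). Oxt was 418 ± 82.5 and 274 ± 63.2 CPM. Het females had 372 to 462 CPM of Avp and WT males 359 to 462 CPM, and neither gene passed with a block by prefix. Id3, an inhibitor of bHLH factors, and the immediate early gene Fos were higher in females by 0.45 and 0.38. Sgk1, a kinase induced by glucocorticoids, was 183 ± 64.0 CPM in females and 415 ± 109 CPM in males, a log2 difference of -1.16 (SE 0.16, limma adjusted p = 0.00267). Tsc22d3, the glucocorticoid-induced leucine zipper gene, Polr3e, an RNA polymerase III subunit, Cdkn1a, a cell cycle inhibitor, and Plekhf1 were lower in females by -0.71, -0.67, -0.66 and -0.61.

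In all, 26 genes passed between the sexes, 10 higher and 16 lower in females, and 17 passed without the 2 libraries in doubt. Prefix 14308 holds males only, so it gives no value, prefix 14309 alone, whose only males are the 2 libraries in doubt, gave 5 genes, and a block by prefix gave 6. Both times these were the 4 Y-linked genes and Arpp21, a striatal phosphoprotein gene named after its values were seen, joined under the block by Eif2s3x, so the hormone and glucocorticoid genes above did not pass within prefixes. With 1 residual degree of freedom taken off 11 passed, and without single libraries the count was 62 without WT replicate 11, 10 without Het replicate 8 or Het replicate 2, 11 without WT replicate 4, WT replicate 6 or Het replicate 9, 13 without WT replicate 7, 14 without Het replicate 7, 15 without Het replicate 4 and 16 without Het replicate 5. With each of the 11 libraries left out in turn, Polr3e did not pass in 4 runs, Id3 in 7, Fos and Cdkn1a in 8, and Kdm5c and Eif2s3x in 9, and the other genes named above as different between the sexes passed in each.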

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

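The tests of exchanged labels, of the weights on the removed factor and of the striatal list without the 2 libraries in doubt were chosen after the result was seen. Libraries were marked where they lay far from the others of their genotype, by the gap to the nearest library over the whole range. This gave 11 results among 274 groups of libraries, and chance alone marks about 1 group in 20.

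Myt1l was 130 CPM in the library labelled Het replicate 9, against 58.7 to 75.9 CPM in the other 5 Het libraries, and 51.1 CPM in WT replicate 11, the lowest WT value. An exchange of these 2 labels may be the cause: Rnaseh1, near Myt1l, placed both libraries with the other genotype, but it was chosen among 19 neighbours after its values were seen. Over 13183 genes, with genotype and sex taken out, Rnaseh1 had the highest correlation with Myt1l between libraries (r 0.966). Nts (0.962) and Mettl14 (0.96), which are not among the 19 neighbours, were nearly as high, so such a match is not particular to this region. A score was taken over 216 genes on other chromosomes that passed the limma threshold between genotypes in the other 9 libraries. It is 0 at the WT mean and 1 at the Het mean of the libraries that set its scale. The score was 1.1 for Het replicate 9 and 0.40 for WT replicate 11, both on the side of their own label. With each scored library left out of its own gene choice and scale, the score was 0.049 to 0.62 for other WT and 0.66 to 0.88 for other Het libraries, so these ranges nearly met. WT replicate 4, at 0.62, lay nearer the Het mean than the WT mean. Striatal markers were higher in Het among the other 9 libraries (median 0.47). Their mean was highest of all in Het replicate 9 (0.658 on the centred log2 scale). The score of Het replicate 9 may therefore follow striatal expression and not genotype, so it cannot count against an exchange. An exchange and a real difference in level thus cannot be told apart here, and genotyping reads over the mutated site would decide. The removed factor is argued against, since the larger of both weights on it was 0.157, and animal-to-animal variation in Myt1l stays open as untested.

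In the library labelled Het replicate 9, Gal was lowest at 227 CPM (others 296 to 331) and Kcna1 highest at 23.9 CPM (others 16.8 to 18.4). In the same library the microglia list mean was 0.116 on the centred log2 scale, against -0.0692 to -0.0341 in other Het libraries. List means not marked by the gap rule were also extreme there. Those of striatum (0.658) and thalamus (0.334) were the highest of any library, with Het replicate 8 next (0.298 and 0.156). The feeding (-0.125), neuroendocrine (-0.161), hypothalamic transcription factor (-0.143) and choroid plexus (-0.456) means were the lowest. The cortical and hippocampal mean (0.0599) was not extreme. Whether this piece held a different share of tissue was not tested. In Het replicate 7, Pmch was 630 CPM (others 309 to 385) and Rpl14 was 1400 CPM (others 1210 to 1240). In Het replicate 5, Emilin2 was 0.461 CPM (others 0.924 to 1.22) and Gjb6 was 335 CPM (others 257 to 279). In Het replicate 4, Ttc9b was 24.1 CPM (others 9.28 to 13.0). Among WT libraries, Tmem252 was 5.16 CPM in replicate 7 (others 3.09 to 3.28) and Gpr17 was 12.2 CPM in replicate 4 (others 14.3 to 15.0).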

How the results depend on the processing

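The runs without the pair of libraries in doubt, with the length and GC trend or the striatal covariate, with a prefix for Myt1l, sex, interaction or lists, with voom or the deposited log2 values, and with centring or quantile normalization of lists were chosen after the data were examined. Where a value below differs from the reported one, the cause was not tested. Fewer libraries or stricter error terms can lower the power, but the genotype count rose to 820 without WT replicate 3. Raw depth is unknown, so what depth limits could not be worked out.

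Het against WT gave 453 genes, and 419 to 542 with other pseudocounts, filters, centring, quantile normalization, robust eBayes, voom or the deposited log2 values. It gave 1163 genes at an adjusted p under 0.1, 189 with residual degrees of freedom reduced, 200 with no covariate, 300 with a prefix block, 6 in prefix 14308, 16 in prefix 14309, 0 in females alone, 1 in males alone (Avp, -0.84), 229 without the pair, 240 with the length and GC trend taken out, and 1 with the striatal covariate (Prune2, 0.57). Leaving out 1 library gave 140 (WT replicate 6) to 820 (WT replicate 3). The labels share replicate numbers 4 and 7, and no label says that these numbers pair animals. Same-numbered libraries did not deviate together (correlations -0.14 and -0.055), but 2 pairs of corrected values cannot decide this. A replicate block on those 4 libraries, with 1 residual degree of freedom, gave 46 genes. The interaction gave 0 genes in every run but prefix 14309 alone, which gave 1 (Myt1l). Female against male gave 26 genes, 25 to 28 with other pseudocounts, filters or centring, 57 at an adjusted p under 0.1, 11 with residual degrees of freedom reduced, 6 with a prefix block, 5 in prefix 14309, 17 without the pair, and 10 (Het replicate 8) to 62 (WT replicate 11) with 1 library left out. Camera called 14 lists, 3 with an estimated correlation, 8 with the length and GC trend taken out, 5 with the striatal covariate, and 11 to 16 with 1 library left out. Of the 14, none reversed in these runs except thalamus in females alone and glucocorticoid response with the striatal covariate. Of the 24 highest and lowest genes, none reversed, 24 passed with a pseudocount of 1, centring or quantile normalization, 23 with no filter, 14 with no covariate, 14 without the pair, and 0 in either sex alone.

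Myt1l was -0.0115 and turned to 0.179 in males alone and 0.313 in prefix 14309, with -0.195 (Het replicate 9) to 0.0904 (Het replicate 5) when 1 library was left out. Apart from the 2 named above, the other reversals were of lists that did not pass, among them monoamine and cholinergic genes (-0.105) and mitochondrially encoded genes (-0.126), and of these lists the mitochondrial and microglia lists passed in some other runs. With centring, hypothalamic transcription factors were at -0.011, MYT family -0.00146, endothelium -0.00597 and ependyma -0.00759. With quantile normalization, immature neurons were at 0.00965 and ependyma at -0.00655, and with no covariate ependyma was at -0.00614. With a prefix block, immature neurons were at 0.00638, Notch and Wnt 0.000354, MYT family -0.0241 and ependyma -0.000227. In females alone, immature neurons were at 0.0113, progenitors 0.0449, Notch and Wnt 0.0824, myelinating oligodendrocytes -0.111, endothelium -0.0607 and thalamus -0.0887. In males alone, hypothalamic transcription factors were at -0.0899, monoamine and cholinergic genes 0.0212, MYT family -0.0667, microglia 0.00491 and ependyma -0.222. In prefix 14308, monoamine and cholinergic genes were at 0.0667, MYT family -0.025 and ependyma -0.137. In prefix 14309, hypothalamic transcription factors were at -0.0456, immature neurons 0.0565 and Notch and Wnt 0.0669. Without genes shared between lists, hypothalamic transcription factors were at -0.016. Without the pair, immature neurons were at 0.00691, progenitors 0.0185, Notch and Wnt 0.0235, myelinating oligodendrocytes -0.0322 and endothelium -0.0406. With the length and GC trend taken out, hypothalamic transcription factors were at -0.00347, MYT family -0.0128, microglia 0.0183, endothelium -0.0128 and mitochondrially encoded genes 0.0704. With the striatal covariate, hypothalamic transcription factors were at -0.0568, immature neurons 0.0365, monoamine and cholinergic genes 0.0816, myelinating oligodendrocytes -0.0345, astrocytes 0.0044, endothelium -0.192, ependyma -0.114 and glucocorticoid response 0.00879. Leaving out 1 library moved hypothalamic transcription factors from -0.0288 to 0.0738, immature neurons from -0.0257 to 0.0295, progenitors from -0.119 to 0.00875, Notch and Wnt from -0.0365 to 0.0364, MYT family from -0.0241 to 0.0867, myelinating oligodendrocytes from -0.0174 to 0.048, endothelium from -0.0541 to 0.0968 and ependyma from -0.0928 to 0.146.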

Other observations

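The lower peptide genes and the higher striatal genes had the same sign in both sexes, with no interaction past the threshold (limma adjusted p of 0.982 for Avp, Gal and Drd1, and 0.986 for Oxt). The genes given here had passed the fit over both sexes, which makes a shared sign likely, so it is no separate support. Avp had a Het minus WT log2 difference of -0.43 in females and -0.84 in males, Oxt -0.45 and -0.52, Hcrt -0.40 and -0.37, and Gal -0.26 and -0.40. Drd1 had 0.95 in females and 0.67 in males, Scn4b 1.02 and 1.12, and Meis2, a transcription factor also found in striatal neurons, 0.60 and 0.51.

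Of the tests in this part, the striatal list without the 2 libraries in doubt, the count of other splits for Het against WT, the splits unrelated to the removed factor, the correlations of list means within groups, the repeatability of slopes, the striatal covariate for the peptide lists and the separate tests of the synapse, risk and ribosomal groups were chosen after the result was seen. Of 100 splits of the libraries into 5 and 6, drawn from 462, 1 gave as many genes as the 453 of the labels, the labels themselves, and the highest other gave 1. For sex, 2 of 100 gave at least 26 genes, the highest other 31. For gene lists, 2 of 100 gave at least 14, the highest other 15 and the median other 5. Of the 462 splits, 7 others, with the split by sex set aside, were as unrelated to the removed factor as genotype (r under 0.01 in size), and they gave at most 1 gene and 12 lists. A correction fitted around genotype and sex takes out hidden variation but leaves the part that lies along these labels, so whether chance can be excluded is left open for all 3 counts. In 8 of 25 simulated sets without a genotype effect, such a correction gave at least 453 calls.

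A candidate explanation for higher striatal markers (median 0.45) beside lower hypothalamic peptides is a larger share of striatal tissue in the pieces dissected from Het mice, while the 2 libraries in doubt are argued against as the source, since the striatal median was 0.47 without them. The planned test asked whether genes that follow the striatal mean within groups also differ between genotypes. Across 12599 genes, which are not independent replicates, r was 0.0204 (-0.0052 to 0.034 with 1 library left out), above 80% of 1000 random lists. The repeatability of both quantities would allow 0.32 to 0.51. With the striatal mean as a covariate, 1 gene passed in place of 453, and 5 lists in place of 14. That mean differs between the groups, so the covariate also takes out part of any genotype difference, and these counts do not decide. The low r argues against tissue share as the whole cause only if the striatal mean within groups follows tissue share. That was not tested, within groups this mean also went with immediate early genes (r 0.82), and slopes in WT and Het libraries correlated at only 0.12. A share that varied along the removed factor would not show either. For the peptide lists taken alone tissue share stays open: with the striatal mean as a covariate the median share kept was 0.466 and both lost their calls, the feeding list at -0.042 (SD over members 0.37) from -0.10 (0.23) and the neuroendocrine list at -0.086 (0.42) from -0.17 (0.28), with smaller medians and a wider spread. Between the 11 libraries within groups of genotype and sex, the feeding list went against the striatal mean (r -0.72, rho -0.70, exact permutation p = 0.157 and 0.0949, r -0.60 without the 2 farthest libraries), while the neuroendocrine list with Avp and Oxt did not follow it (r -0.025, rho 0.091, p = 0.951 and 0.812, r 0.44), and adjusted over 29 lists these p were 0.583 and 0.393, and 0.951 and 0.872, while the 2 lists whose r passed were immediate early genes (0.82, adjusted p = 0.0335) and risk genes (-0.84, adjusted p = 0.0335), neither of them by rho (0.0671 and 0.067). For the 2 peptide lists a different share of tissue and a change within hypothalamic cells, the biological explanation by genotype, therefore cannot be told apart, and in situ hybridisation of Drd1 and Avp would test it.

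Another hypothesis concerns synapse, channel and risk genes that were higher while ribosomal and respiratory chain genes were lower, since the first are long and the second short, with genotype open as the biological explanation for each part. After each library's trend on transcript length and GC content was taken out, the median size over the 5 lists was 0.341 of its value before, but this hid unlike parts. For each part, the share kept was taken list by list, and its median over the lists is given. This share was 0.605 for synapse (0.096) and channel genes (0.17), both still past the threshold (camera adjusted p = 0.000867), which argues against the trend as their whole cause. It was 0.232 for risk and respiratory genes, whose calls ended as their medians fell, from 0.17 (SD over members 0.23) to 0.030 (0.23) and from -0.16 (0.054) to -0.047 (0.070), so a length or GC trend fits this part, although the trend may be biological. For ribosomal genes the share was 0.345 with the call kept (-0.059, camera adjusted p = 0.0133), so a trend and a change of these genes cannot be told apart. With the striatal covariate the median size over the 5 lists was 0.971 of its value before. Taken list by list, the median share kept was 1.05 for the 3 higher lists, all still past the threshold. This argues against striatal tissue as the whole cause of these 3 lists, as far as the striatal mean follows that tissue. A share that varied along the removed factor would not be adjusted for. For risk genes, the negative r within groups and the higher value with the covariate are 1 observation and not 2 arguments. For the 2 lower lists the share was 0.255, and striatal tissue stays open as a cause. Ribosomal genes lost their call (-0.016, SD over members 0.098, from -0.17, 0.046) and respiratory genes did not (-0.067, camera adjusted p = 0.0471).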
